A study of Canis lupus familiaris with 6 samples.

How the data were processed

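RNA was sequenced from 6 samples of cultured canine mammary gland tumour cells, 3 of the cell line M5 and 3 of the cell line M25, all at passage 25. Per the labels' protocols, total RNA was extracted with TRIzol from triplicate biological samples of each line, RNA integrity was checked on a Bioanalyzer, and mRNA libraries were made with the Illumina TruSeq RNA kit, which does not mark the strand. The submitters' processing notes name FastQC, TopHat2 version 2.0.9, Bowtie2 version 2.1.0, SAMtools, HTSeq and the genome build CanFam3.1. The annotation release, the counting settings and any read filters are not given in the sources used here. Because the libraries do not mark the strand, reads of overlapping genes on opposite strands cannot be told apart, and genes with near-identical copies have uncertain counts.

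The deposited values are whole-number read counts per Ensembl gene, 1 table per library, with no normalization. Each table holds 24580 gene identifiers and 5 rows that name no gene. Those 5 rows were kept out of library sizes and tests. Their reads made up the rest of the counted reads: the share assigned to no annotated gene was 21.4% to 22.4% in the M5 libraries and 23.0% to 23.9% in the M25 libraries, the share aligned in more than 1 place was 2.34% to 4.20% and 2.45% to 2.72%, and the ambiguous share was 0.449% to 0.688% and 0.484% to 0.523%. The gene rows summed to between 17581703 and 22388371 counts per library. A count of 3, taken as the floor that a count of 0 allows, corresponded to 0.135 to 0.175 CPM (counts scaled to a common library size) over the 6 libraries. This floor and the counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

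The count tables do not pair the identifiers with gene names. The reference gene table used here, with 43286 genes, holds 0 Ensembl identifiers, so 0 of the 24580 identifiers were matched to a symbol or a position. The comparisons that need names or positions were therefore not analysed here: 30 gene lists, a marker panel and a test by chromosome. The comparisons, the rule for naming genes and the alternatives listed at the end of this section were fixed before the data were examined. Genes are given by identifier, and at most 2 that were higher and 2 that were lower in M25 are printed.

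The comparison between the lines was fitted with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with robust estimation on all 6 libraries and cell line as the only term. Genes were filtered with filterByExpr at its default minimum count of 10, which left 12851 genes and at least 99.9% of the gene counts of each library, and were scaled with TMM. A positive log2 fold change means higher in M25. Genes were called at an adjusted p (Benjamini-Hochberg) below 0.05, and again with a fold change of at least 2. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Normalised values are CPM on the TMM-scaled library sizes. Principal components and correlations used log2 CPM with a prior count of 2. Measures per library were compared between the lines with a two-sided exact permutation test, whose smallest p is 0.1 with 3 libraries against 3.

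The genes printed follow a fixed rule: called, at least 2-fold, at least 10 CPM on average in the higher line and no overlap between the libraries of the lines, ranked by log2 fold change. The rule also required a symbol, which was dropped because no identifier had one. Its parts on gene lists and on a marker panel gave no gene for the same reason.

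No replicate pair was 1 library deposited again: counts differed between replicates by 4.99 to 41.0 times the variance that sampling alone gives (chi-square per degree of freedom over genes with at least 20 counts in the pair). Without 7 genes that varied at least 4-fold between M5 replicates, the highest value, that of M5 replicates 1 and 3, fell from 41.0 to 5.45, and the range was 3.14 to 7.91. Per the labels' protocols the replicates are biological samples of each line, without saying whether they were cultured separately, so the p-values measure only the spread between these samples, and they describe these 2 lines. The procedure was tested on simulated data for the comparison of M25 with M5, in 5 simulated sets of 12719 to 12744 tested genes with 200 changed genes each. edgeR recovered 72.5% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 96.7% of those changed 4-fold, with median estimates of 1.51-fold, 2.02-fold and 4.02-fold. Of its 950 calls, 83 (8.74%) were unchanged genes, a share above the nominal one. The simulated changes were equally often up and down, at most 4-fold, and in far fewer genes than were called between the lines. These shares therefore need not hold for the real comparison.

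The alternatives were DESeq2 size factors, upper-quartile factors, library totals alone, no low-count filter, a filter at 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom (limma 3.58.1), edgeR's glmTreat against a 2-fold change, a replicate block, scaling without the 50 most abundant genes, and leaving out each library. Alternatives for the gene set tests were not run.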

Results

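Gene expression was measured by RNA sequencing in the cell lines M5 and M25, both established from canine mammary gland tumours and sampled at passage 25. Each line was represented by 3 libraries. The libraries held 22388371, 20000112 and 18544733 gene counts for M5 replicates 1, 2 and 3, and 20976864, 20833214 and 17581703 for M25 replicates 1, 2 and 3. Of the 24580 annotated genes, 6837 had no count in any library and 12851 were abundant enough to test. The design implies 1 comparison, M25 against M5, which asks how the transcriptomes of the lines differ.

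Libraries of the same line resembled each other more than libraries of different lines. Across genes, which are not independent replicates, Pearson's correlation of log2 CPM was 0.987 to 0.993 between replicates of a line and 0.937 to 0.943 between lines. The first principal component separated M5 from M25 and held 80.8% of the variance. The second component held 6.86% and set M25 replicate 3 apart from the other M25 replicates. The biological coefficient of variation between replicates was 7.41% in M5 and 7.93% in M25.

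**Figure D1:**
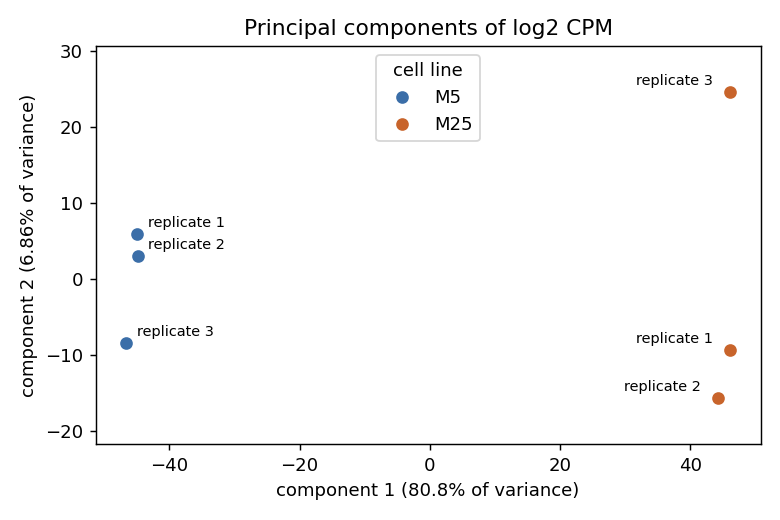
The 6 libraries on the first and second principal components of log2 CPM over the tested genes, coloured by cell line. Component 1, with 80.8% of the variance, separates the lines, and M25 replicate 3 lies apart on component 2, with 6.86%.

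Most tested genes differed between the lines, in about equal numbers each way under TMM scaling. With edgeR's quasi-likelihood test, 7264 of 12851 genes (56.5%) passed an adjusted p of 0.05; 3637 were higher and 3627 lower in M25. Most differences were small: the median absolute log2 fold change of the called genes was 0.50, and 4207 of them changed by less than 1.5-fold. The libraries of the lines did not overlap in 6975 of the 7264 called genes, and in 61.6% of all tested genes, where chance gives 10%. The balance between higher and lower genes depended on the scaling. TMM left the median log2 fold change of all tested genes at 0.006. Such centring favours an even balance, which is therefore not a result about the lines by itself. With library totals alone the median log2 fold change of all genes shifted by 0.16, and 69.3% of called genes were higher in M25, against 50.1% with TMM.

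Large differences were more often increases in M25, mainly among the less abundant genes. Among those with at least 10 CPM on average in the higher line and no overlap between the lines, numbers were near equal, 291 higher and 286 lower in M25. At least 2-fold differences were found for 1528 genes (11.9% of those tested), of which 911 were higher and 617 lower in M25; 59.6% were thus higher in M25, and 70.6% with library totals alone. At 4-fold or more the counts were 303 higher and 184 lower, at 8-fold or more 135 and 80, and at 32-fold or more 27 and 25. When the test was made against a 2-fold change instead of no change (edgeR's glmTreat), 795 genes passed, 462 higher and 333 lower in M25.

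**Figure D2:**
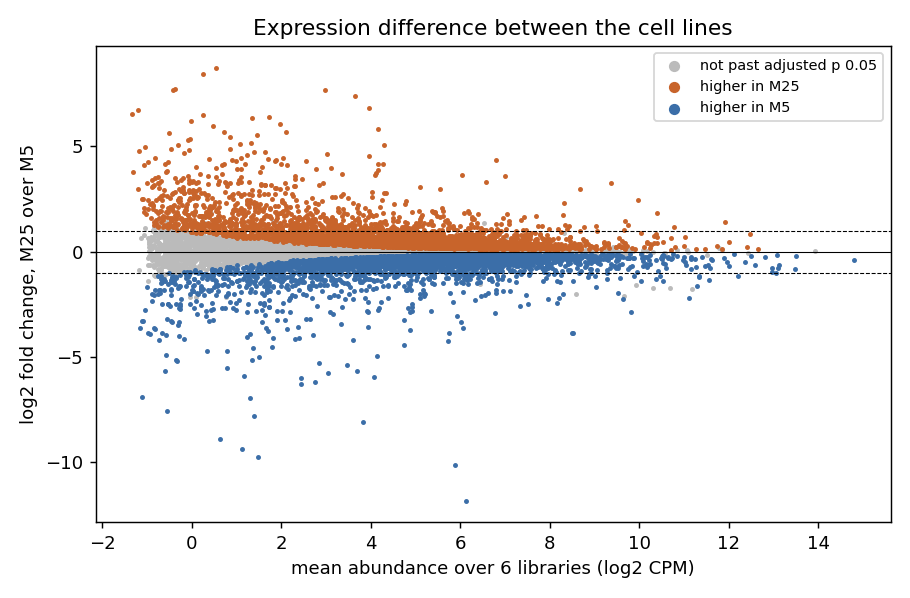
Log2 fold change of M25 over M5 against mean abundance in log2 CPM for the 12851 tested genes, with genes past an adjusted p of 0.05 coloured by the line in which they were higher and dashed lines at 2-fold. With TMM scaling, which favours an even balance, the called genes fall on both sides in near-equal number, 3637 higher and 3627 lower in M25.

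Of the called genes with at least 2-fold differences, 577 had no overlap between the lines and at least 10 CPM on average in the higher line, 291 higher and 286 lower in M25; genes below that level, some with larger fitted fold changes, were not ranked. Among the 577, the 2 most increased in M25 were ENSCAFG00000015893 and ENSCAFG00000001968. ENSCAFG00000015893 had 15.4 ± 1.29 CPM in M25 and 0.0658 ± 0.0698 CPM in M5 (SD, n = 3 each), with an edgeR log2 fold change of 7.67 (SE 0.31, adjusted p = 1.38e-15). ENSCAFG00000001968 had 24.8 ± 0.366 CPM in M25 and 0.142 ± 0.110 CPM in M5 (SD, n = 3 each), with an edgeR log2 fold change of 7.42 (SE 0.23, adjusted p = 1.29e-17). The M5 values rest on 4 and 8 counts over the 3 libraries, so that the ratio of M25 to M5 had a 95% counting interval (exact binomial) of 86.7 to 819 for the first gene and 90.5 to 415 for the second. These few counts set the fold. Without M5 replicate 1 the log2 fold change of ENSCAFG00000015893 was 8.82, and without M5 replicate 2 that of ENSCAFG00000001968 was 8.20. The standard errors of these 2 genes come from the F statistic and are smaller than counting error on so few counts. They understate the uncertainty of the fold, for which the counting intervals are the better guide.

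The 2 most decreased of the 577 genes in M25 were ENSCAFG00000032384 and ENSCAFG00000030958. ENSCAFG00000032384 had 140.6 ± 4.27 CPM in M5 (SD, n = 3), and its M25 libraries held 2 counts in replicate 1 and 0 in the others, against 8133 counts in M5. The ratio of M5 to M25 was 4413 with a 95% counting interval of 1221 to 36450, and the edgeR adjusted p was 1.07e-23. Without M25 replicate 1, M25 was at 0 and the gene was at least 1896-fold higher in M5 (against 3 counts over the remaining M25 libraries). ENSCAFG00000030958 had 117.2 ± 3.86 CPM in M5 and 0.0926 ± 0.117 CPM in M25 (SD, n = 3 each), from 6776 and 6 counts, a ratio of 1226 with an interval of 563 to 3341 (edgeR adjusted p = 1.18e-20). Of the 6 counts, 5 came from M25 replicate 1, and its fitted log2 fold change of -10.17 became -11.88 without that library and -9.58 without M25 replicate 2. The count files give no names for these 4 genes.

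**Figure D3:**
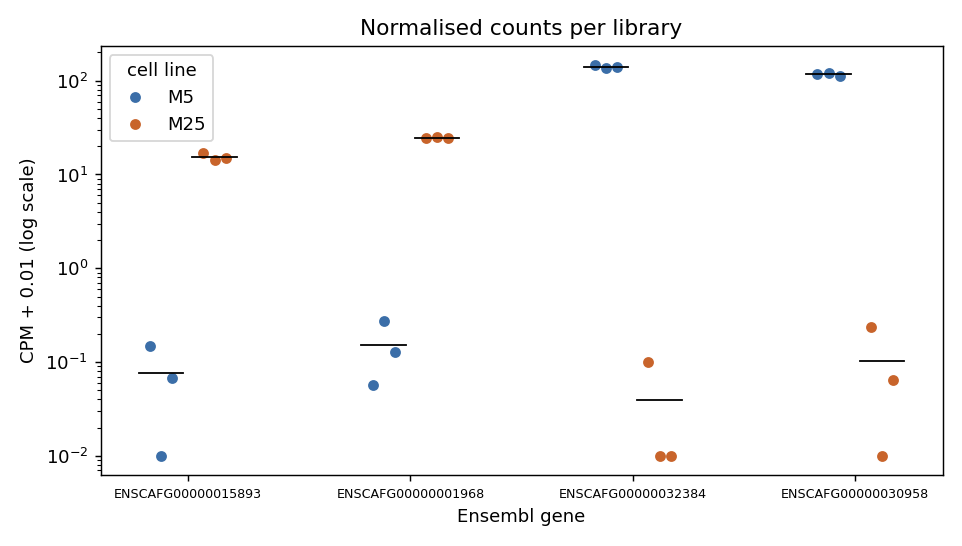
Normalised counts (CPM + 0.01, log axis) of the 2 genes most increased and the 2 most decreased in M25 among those with at least 10 CPM in the higher line, with 1 point per library, coloured by line, and a bar at the mean of the 3 libraries. Libraries of the higher line lie within 14.3 to 145.3 CPM, and points at the lower edge are libraries with 0 counts.

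Expression in 1 line with near-silence in the other was found for few genes at a strict cutoff. 19 genes had a mean of at least 1 CPM in M25 and at most 3 counts in the 3 M5 libraries together, and 11 genes had the reverse pattern. The highest mean was 4.78 CPM among the 19 genes and 140.6 CPM among the 11. These numbers depend on the cutoff of 3 counts. ENSCAFG00000015893, ENSCAFG00000001968 and ENSCAFG00000030958 fell outside it, with 4, 8 and 6 counts in the lower line, though their levels were higher than 4.78 CPM in the other. In each set, 4 genes had 0 counts in every library of the silent line. Without M25 replicate 1, 17 genes instead of 11 were on in M5 and off in M25, at a mean of at most 1 count per library. The number was 16 without M25 replicate 2 and 13 without M25 replicate 3. With any M25 library left out, fewer libraries had to be near-silent.

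The direction of the difference varied with abundance. Among the 100 most abundant genes, 61 were called lower and 25 higher in M25, with a median log2 fold change of -0.26 and a range of -2.21 to 1.83. With library totals alone, where the median log2 fold change of all genes shifted by 0.16, these counts were 48 lower and 34 higher, and the median was -0.09. Both lines shared 78 of their own 100 most abundant genes. The 100 most abundant genes of each library took 36.5% ± 0.929 of gene counts in M5 and 32.4% ± 0.419 in M25 (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible, and 0.183 after Benjamini-Hochberg adjustment over 11 measures per library). The most abundant gene alone took 3.103% ± 0.0556 in M5 and 2.59% ± 0.0796 in M25, with the same p.

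In the decile of tested genes with the lowest mean abundance, the balance was the other way. Of these 1286 genes, 319 were called at least 2-fold higher and 148 at least 2-fold lower in M25, and their median log2 fold change was 0.28. With a filter at 1 CPM in 3 libraries these counts were 174 and 68. They cover only those genes of this decile that passed that filter, which left 12184 genes in all, so they are not out of 1286. In the most abundant decile, 31 were at least 2-fold higher and 48 at least 2-fold lower. The share of genes called at any size rose with abundance, from 39.7% in the lowest decile to 75.6% in the highest. Smaller differences can be called at higher counts, and calls at 2-fold or more were fewer in the highest decile. The rise therefore does not show that abundant genes differed more.

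**Figure D4:**
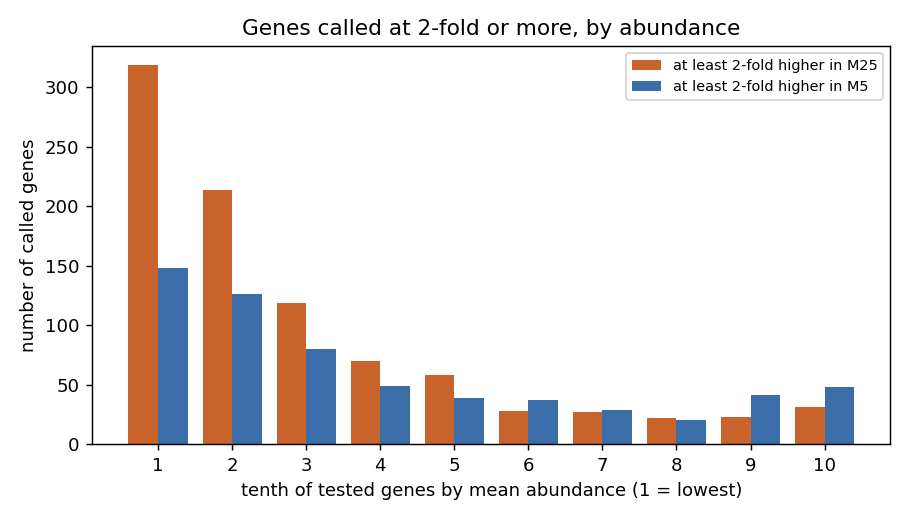
Number of genes called at 2-fold or more in each decile of the tested genes, from the lowest (1) to the highest (10) mean abundance, with genes higher in M25 and genes higher in M5 as separate bars. In the lowest decile 319 genes were higher in M25 and 148 in M5; in the highest decile the numbers were 31 and 48.

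More genes were detected in M25. At least 1 count was found for 15696 ± 186 genes per M25 library and 15345 ± 116 genes per M5 library (SD, n = 3 each; two-sided exact permutation p = 0.1, adjusted 0.183). With every library thinned to 17581703 counts, the expected numbers were 15571 ± 78.4 and 15193 ± 19.98, and each M25 library lay above each M5 library. The share of reads assigned to no annotated gene was also higher in every M25 library, at 23.4% ± 0.471 against 22.004% ± 0.504 (SD, n = 3 each; two-sided exact permutation p = 0.1, adjusted 0.183).

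A small group of abundant genes varied between replicates of M5. Of 8445 genes with a mean of at least 10 CPM in M5, 7 differed by at least 4-fold between M5 replicates, by 11.996-fold to 45.8-fold. Together they took 0.144% of gene counts in M5 replicate 1, 0.710% in replicate 2 and 2.39% in replicate 3, and 0.252% to 0.432% in the M25 libraries. Their mean levels were lower in M25, with log2 fold changes of -2.13 to -1.55, but 0 of the 7 passed edgeR's test (adjusted p 0.237 to 0.339). None of them reached an unadjusted p of 0.05 there, and 0 were called by DESeq2 or limma-voom. The 7 genes were chosen for their spread between M5 replicates, which enters the error of each test. These outcomes could thus be foreseen and do not show whether the lines differ in these genes. In M25, 3 of 8530 genes varied at least 4-fold, 1 of them among the 7.

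**Figure D5:**
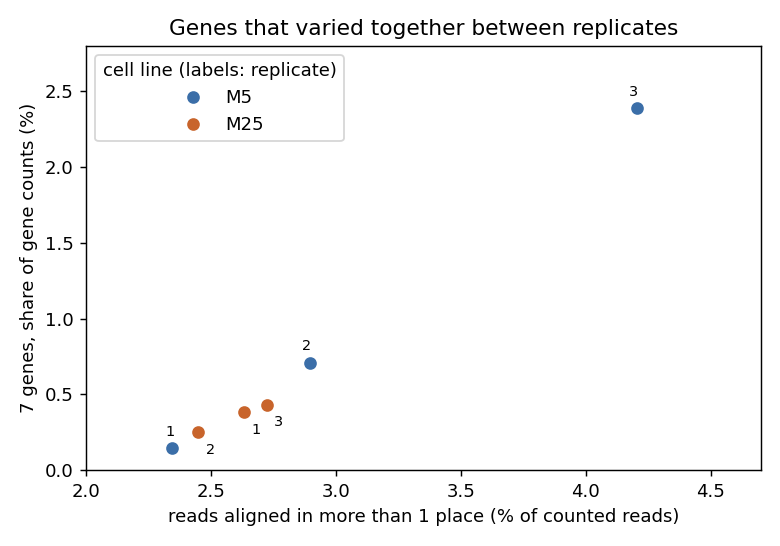
Share of gene counts taken by the 7 genes that varied at least 4-fold between M5 replicates, against the share of counted reads aligned in more than 1 place, both in percent, with 1 point per library labelled by replicate number. M5 replicate 3 stands apart at 2.39% and 4.204%, and the other libraries lie between 0.144% and 0.710%.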

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

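The tests in this part, on reads aligned in more than 1 place and on 7 genes that varied within M5, were chosen after the result was seen. The comparison used only reads assigned to genes. Of the reads outside it, 2 shares are described here, and the share aligned in more than 1 place was tested further. Reads assigned to no annotated gene made up 23.4% of counted reads in M25 and 22.004% in M5 on average. Every M25 library lay above every M5 library, but the two-sided exact permutation p was 0.1, and 0.183 after Benjamini-Hochberg adjustment. Reads aligned in more than 1 place made up 4.204% of counted reads in M5 replicate 3, against 2.34% to 2.89% in the other libraries.

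The 7 genes that varied at least 4-fold between M5 replicates moved together: the correlation of log2 CPM between pairs of them over the 6 libraries had a median of 0.985 and a minimum of 0.913. Their share of gene counts followed the share of reads aligned in more than 1 place over the 6 libraries, with Pearson's r = 0.997 (exact permutation p = 0.00139, the smallest the permutations can give) and Spearman's rho = 1 (exact permutation p = 0.00278, also the smallest possible; both 0.00278 after Benjamini-Hochberg adjustment over 2 tests). These p-values are descriptive: the permutations exchanged libraries freely between the lines, and the 7 genes were chosen for their spread between M5 replicates. Without M5 replicates 1 and 3, the libraries farthest from the median, r was 0.968 over 4 libraries. Within each line the 3 libraries ranked in the same order on both measures, and no correlation was computed over 3 libraries. The share of the 7 genes also correlated with the share of ambiguous reads over the 6 libraries, at Pearson's r = 0.972, though the order within M25 differed. A high r was thus not particular to reads aligned in more than 1 place. A candidate explanation is RNA present in several genomic copies, in unequal amounts between the libraries, but the identities of the 7 genes were not analysed here, and a difference between the samples themselves stays open. Whether the lines also differ in these genes cannot be told apart from the spread within M5: 0 of the 7 were called by edgeR, and the smallest adjusted p was 0.237.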

How the results depend on the processing

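The alternatives that leave out replicate 3 of both lines, or the 7 genes that varied within M5 were chosen after seeing the data. The count of called genes stayed between 6514 and 7276 when each library was left out in turn. The count at 2-fold or more stayed between 1513 and 1640. The share of called genes higher in M25 stayed between 49.2% and 50.3%, with TMM scaling in each case. Over the other alternatives the counts stayed within 1.5 times 7264 and 1528, except with glmTreat against 2-fold, where both became 795 because the test itself is stricter; among the 100 most abundant genes it left 8 lower and 3 higher. In the lowest abundance decile glmTreat left 126 higher and 55 lower in M25. All of these 795 genes were among the 7264. With library totals alone the share higher in M25 was 69.3% (5243 higher and 2318 lower), the median log2 fold change being shifted by 0.16, and 5955 genes were called under both scalings. DESeq2's Wald test called 6739 genes, 6711 of them among the 7264. The replicate numbers of the lines did not pair the libraries: the deviations of same-numbered libraries correlated at -0.06, -0.04 and -0.10, and 0 of the 6 libraries correlated best with their own number. With a replicate block 6850 genes were called, 1507 of them at 2-fold or more. Leaving out M5 replicate 3 together with M25 replicate 3 gave 7108 and 1656 genes, and leaving out the 7 genes that varied within M5 gave 7278 and 1541. The 4 genes given by identifier stayed called in the same direction under all 18 alternatives, with a largest edgeR, DESeq2 or limma adjusted p of 1.14e-07. Of the 10 splits of the 6 libraries into 3 and 3, only the real one called any gene with edgeR: 7264 against a highest of 0 in the others, where at most 250 genes reached an unadjusted p of 0.05 and DESeq2 called at most 1. The number of splits with as many calls was 1, and 10 splits are too few for a share below 0.05. Every other split also put libraries of both lines in each group, so the difference between the lines added to the spread within groups. Few calls there could be foreseen, and they do not gauge the 7264. A count of 0 in a library allows a level of up to 0.135 to 0.175 CPM, so that depth does not show absence below it. The gene list and chromosome alternatives were not run.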

Other observations

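The test of depth, the count of M5-detected genes at 0 in M25 and the comparison of single libraries in this part were chosen after the result was seen. M25 replicate 3 differed from its fellow replicates mainly by decreases: of 8542 genes at 10 CPM or more on average, 29 were at least 2-fold lower and 1 at least 2-fold higher in it than in the mean of the other M25 libraries. In each of the other libraries, 0 to 7 genes were at least 2-fold lower and 1 to 7 at least 2-fold higher than in the rest of their line. In total 1115 genes had counts in M25 only and 763 in M5 only.

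The larger number of detected genes in M25 was weighed against technical explanations. Unequal depth is argued against, since after thinning to 1 depth the mean gap between the lines was 378.1 genes, and the lowest M25 library was 267 genes above the highest M5 library. The larger share of M5 reads taken by abundant genes is argued against as the whole cause: without the 100 most abundant genes, 83.02% of the gap was left, with every M25 library above every M5 library. Reads spread evenly over genes stay open: over 3939 genes with 1 to 20 counts in all libraries together, M25 held 1.23 times the scaled counts of M5, and 46.3% of that excess was left without the 10% of genes with the largest differences, between the bounds of 25% and 75% set for a decision. A wider set of expressed genes in M25, a difference between the lines themselves, also stays open and was not tested. Nor was the gap tested against the share of reads assigned to no annotated gene, which was also higher in every M25 library.

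For the excess of 2-fold increases among the least abundant genes, evenly spread reads could be weighed only at 0.368 CPM or more. Reads at that level are argued against by a count over genes chosen from M5 alone, but this could be foreseen. Of all annotated genes, 6837 had no count in any library. Of 14955 genes with at least 3 counts in M5, 136 had 0 counts in M25. The smallest excess among the 319 genes of the lowest abundance decile that were at least 2-fold higher in M25 was 0.368 CPM, and reads spread evenly at that level would leave 1.42e-06 of the 14955 genes at 0. The median excess of the 319 genes, 0.957 CPM, was 22.3 times the mean level of the untested genes in M25 (0.0430 CPM, against 0.0353 CPM in M5). The choice of both sets of genes raises this ratio, so no conclusion is drawn from it. The level of 0.368 CPM itself came from genes chosen as higher in M25. Even reads at a lower level, added to counting noise, were not tested and stay open as a cause of the excess. Extra reads spread unevenly, for example with gene length, were not tested.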
